A study of Mus musculus with 8 samples.

How the data were processed

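The series holds 8 Agilent mouse expression arrays with 2 colours each, so 16 tumours were measured, each in 1 channel of 1 array. The tumours grew from pieces of MMTV-PyMT mammary tumours placed into the mammary fat pad of FVB mice, and some of the mice received RANK-Fc, a decoy receptor that binds RANK ligand, at 10 mg/kg 3 times a week, per the labels' protocols. The labels give 6 groups over 2 passages: passage 1 control (2 tumours), passage 1 RANK-Fc (3), passage 2 control (2), passage 2 with RANK-Fc in passage 2 alone ("current", 3), passage 2 with RANK-Fc in passage 1 alone ("prior", 3) and passage 2 with RANK-Fc in both passages ("prior and current", 3). The labels call the treatment named prior here neoadjuvant and the one named current adjuvant, with group codes such as FC_CT. That the neoadjuvant treatment was given in passage 1 is a reading of these codes. Each tumour came from a different animal by its label, and the labels do not say which passage 1 tumour each passage 2 tumour grew from.

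Images were read with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited array files give the median pixel intensity and the median local background intensity of every spot in both colours, as linear values that no one had normalised between arrays, per the file headers. They also give processed intensity values that Feature Extraction had corrected for background, spatial trend and dye, and the log10 ratio of the red over the green processed value, per the file headers. The remaining columns used are other quality marks, coded 0 or 1 per spot, for signal well above background, saturation and uneven pixels, per the file headers. A further deposited table of normalised log ratios has 8 columns whose names match no label, so it was not used in any step. All arrays lay on 1 slide and carried 1 scan time, so no slide or scan batch could be modelled. The direction of each log10 ratio was checked against the channels: it correlated with red over green on each of the 8 arrays, with r from 0.904 to 0.950 across spots.

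Each array held 62976 spots, of which 59305 were not controls and gave 55681 distinct probes. Median intensities were background corrected with normexp at an offset of 50, normalised within arrays by loess and between arrays by Aquantile, and kept on the log2 scale. Between 239 and 337 spots per array that Feature Extraction had marked as uneven or as outliers were set to missing, and repeated spots of a probe were averaged. Probes were named through the accessions in the array files and a RefSeq gene table of assembly GRCm38.p6. That assembly differs from the mm9 design of the array, so the table served for names only and no coordinates were printed. A symbol was found for 28026 of the 55681 probes; 27655 probes without a symbol were left out. A probe passed the filter if it was well above background in every tumour of at least 1 of the 6 groups, and the brightest passing probe stood for its gene, which left 14147 genes; 25.8% of them had several passing probes to choose from. The number of arrays limits the precision of every value; signal well above background was found for 47.5% to 56.5% of the spots of a channel, and no spot was saturated.

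Tests used R 4.3.3 with limma 3.58.1, statmod 1.5.0, jsonlite 2.0.0 and the data.table package at 1.17.8; figures used Python 3.11.15 with matplotlib 3.10.9. The 16 channels were fitted together by lmFit with 6 group means and a dye term, with the 2 channels of an array weighted by the intraspot correlation, followed by eBayes. Benjamini-Hochberg adjustment ran over the 14147 genes of a comparison, with an adjusted p under 0.05 as the threshold, and fold changes are given on the log2 scale with the standard error (SE) of the fit. Group means are given with the standard deviation (SD) over tumours. For a gene above background in no tumour of 1 group, a fold given as "at least" is a point value without sampling error. There were 10 comparisons: current RANK-Fc averaged over 3 backgrounds, current RANK-Fc in each background, prior RANK-Fc alone, prior and current RANK-Fc together, prior RANK-Fc averaged over both passage 2 backgrounds, the interaction of prior and current RANK-Fc, the difference of the RANK-Fc effect between the passages, and passage 2 against passage 1 controls. The residual degrees of freedom were 9.

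The fit was tested on simulated data with the means, dye effects and spread of the real genes and 100 genes changed by each of 2 fold sizes. The first run called too many unchanged genes, and simulations of this design showed that limma's estimate of the intraspot correlation was biased upward. The estimate was therefore corrected by simulating 4000 genes at each of a series of known correlations, which moved it from 0.419 to 0.214. This correction was put in after the counts with the uncorrected estimate had been seen; those counts are given as an alternative. With the corrected value, genes changed by 1 on the log2 scale were recovered at 100% for current RANK-Fc averaged, 98% for prior RANK-Fc averaged, 89% for RANK-Fc in passage 1, 85% for current RANK-Fc in passage 2, 90% for prior RANK-Fc in passage 2, 80% for prior and current RANK-Fc, 90% for current after prior RANK-Fc and 68% for the controls of both passages. Recovery at a log2 change of 2 lay between 94% and 100% for these comparisons, no gene was called in the wrong direction, and between 7 and 18 unchanged genes per comparison were called, out of 14147 tested. The simulated errors were independent between genes and had the same spread in every group, and the changed genes themselves ease the adjustment. Recovery in the real data may therefore be lower, so a gene without a call may still have changed by 1 or more. Of 27 lists tested, 1 was raised by 0.5 in the simulation of current RANK-Fc; it was called with a preset and with an estimated correlation, and the preset also called 2 lists that had not been raised.

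There were 27 gene lists, written with the comparisons, the rule for named genes and the other settings to be tried before the data were examined. They cover RANK pathway components, NF-kB target genes, milk proteins, milk lipid synthesis, AP-2 factors, luminal progenitor, hormone-sensing and general luminal markers, basal, squamous and stem cell markers, proliferation, apoptosis, epithelial-mesenchymal transition, fibroblast, adipocyte, endothelial, macrophage, neutrophil, T and NK cell, B cell, erythroid and skeletal muscle markers, interferon response, hypoxia, immediate early genes and steroid response. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 27 lists of a comparison. Because calls with the preset were lost with the estimate, an exact permutation of the list mean per tumour, with labels exchanged within backgrounds, was added after these results had been seen. The 100 genes with the highest and the 100 with the lowest moderated statistic for RANK-Fc in passage 1 were tested in the passage 2 comparisons with fry.

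Named genes follow a rule. For current RANK-Fc averaged and RANK-Fc in passage 1 these are the 10 genes per direction with the largest change among genes past the threshold whose treated tumours all lay beyond the controls in every background compared. For the other comparisons they are 5 per direction. Where fewer than 5 qualified, the genes of smallest unadjusted p filled the direction up to 5, as values that did not pass. Ligand and receptors of the RANK system and up to 3 members of each list were added. Tnfsf11, the gene of RANK ligand, was not among the genes tested, because no probe of it passed the filter.

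Alternatives were Agilent's processed intensities, no background subtraction, quantile normalisation over 16 channels, median centring in place of loess, no filter, a filter on all channels, the mean of a gene's probes, independent channels, no dye term, log ratios alone, a fit on the groups compared alone, a trended robust variance, and leaving out each tumour in turn. The array files hold no mean signal, so the fit without background subtraction used the median intensities. Added after seeing the data were the uncorrected intraspot correlation and leaving out together the 2 tumours with skeletal muscle signal.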

Results

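Gene expression was measured in 16 MMTV-PyMT mammary tumours of mice, grown as transplants over 2 passages with or without RANK-Fc, a decoy receptor that binds RANK ligand. Of 14147 genes tested, the largest differences lay between the passages and between passage 2 tumours with and without RANK-Fc in the earlier passage. The first principal component held 33.15% of the variance and parted the 5 tumours of passage 1, with scores from 18.29 to 39.79, from the 11 of passage 2, with scores from -39.20 to 6.82. Within passage 2, the 6 tumours with prior RANK-Fc scored between -15.36 and 6.82, and the 5 without it between -39.20 and -7.66. The median correlation of log2 intensities across genes was 0.986 for the 14 pairs of tumours of a group and 0.979 for the 98 pairs from different groups and arrays. Genes are not independent replicates. In each channel 47.5% to 56.5% of the spots were well above background.

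**Figure D1:**
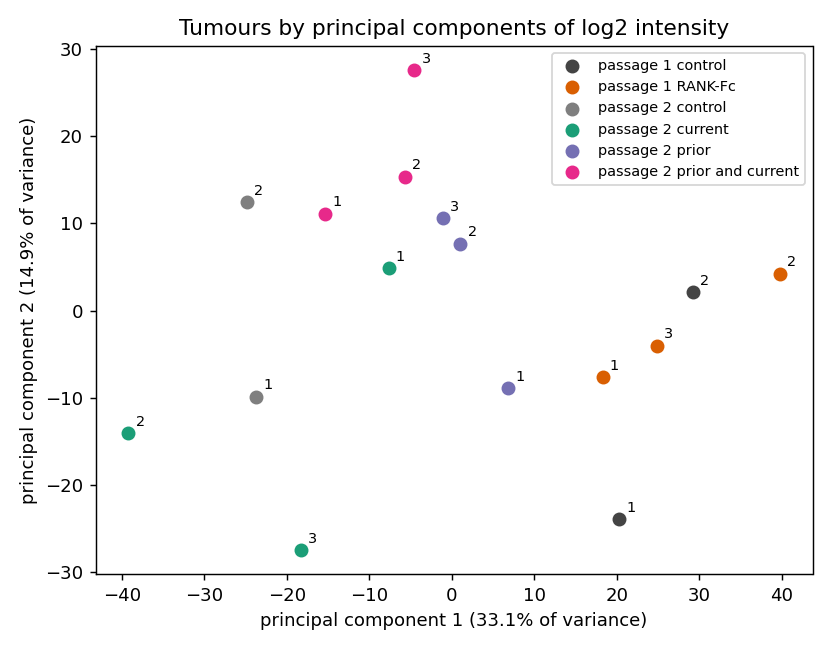
Each point is 1 of the 16 tumours, placed by its scores on the first principal component (horizontal axis, 33.15% of the variance of log2 intensity) and the second (vertical axis, 14.9%), and the digit is its replicate number. Passage 1 tumours score 18.29 or more on the first component and passage 2 tumours 6.82 or less.

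RANK, the receptor gene Tnfrsf11a, was measured at a mean log2 intensity of 12.61 ± 0.003 (SD, n = 2) in passage 2 controls and 12.58 ± 0.37 (SD, n = 3) with current RANK-Fc. Averaged over the 3 backgrounds, it differed by 0.04 ± 0.11 (SE) with current RANK-Fc. Tnfrsf11b, the gene of the natural decoy receptor osteoprotegerin, differed by -0.02 ± 0.22 (SE). Neither passed the test (adjusted p = 0.980 and 0.993), and the ligand gene Tnfsf11 was too dim to be tested.

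What RANK-Fc given in the current passage did was asked first, as the mean of its effect in passage 1, in passage 2 and in passage 2 after prior RANK-Fc. No gene passed the limma test in either direction, while 933 genes had an unadjusted p under 0.05 against 707 expected by chance. Such counts vary widely: of 99 other splits of the tumours within their backgrounds, 26 had as many or more. The smallest p belonged to Pip, a secreted protein of mammary, salivary and lacrimal gland, at a log2 difference of 1.63 ± 0.23 (SE, adjusted p = 0.166). Next came Asns, asparagine synthetase, at 0.58 ± 0.10, Cyp51, an enzyme of cholesterol synthesis, at 0.40 ± 0.07, and Cyb5b at 0.42 ± 0.07, each with an adjusted p of 0.211, and Lcn10, a lipocalin, at 0.61 ± 0.11 (0.320, above background in 5 of the 9 tumours with current RANK-Fc and in none of the 7 others). On the lower side stood Cpsf4l at -0.54 ± 0.09 (0.211), the peptide transporter gene Slc15a2 at -0.53 ± 0.10 (0.237), Snorc at -0.53 ± 0.11, Obi1 at -0.26 ± 0.05 and the anti-apoptotic Bcl2 at -0.34 ± 0.07. The count was 0 under each of the 13 other settings. It was 4 without prior and current replicate 2, 2 without passage 2 control replicate 1, and 1 without current replicate 1 or without passage 1 control replicate 2.

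Genes of milk secretion lay higher with current RANK-Fc. Of 32 measured milk protein genes, 30 had a positive difference and the list mean was 0.57. None passed over all genes, and 5 rose when adjusted over the list alone, among them the casein genes Csn1s2a (2.97 ± 0.67, SE), Csn2 (2.66 ± 0.77) and Csn1s1 (2.01 ± 0.51). The list was called higher with the preset correlation (adjusted p = 6.9e-11) but not with an estimated one (adjusted p = 0.289 with an estimated correlation). Milk lipid synthesis had 19 of 24 members higher, a mean of 0.22 and 4 members that rose when adjusted over the list alone: Insig1 (0.54 ± 0.10), Acaca (0.42 ± 0.12), Scd2 (0.27 ± 0.07) and Gpat4 (0.25 ± 0.08). Its adjusted p was 1.16e-07 with the preset and 0.289 with an estimated correlation. By an exact permutation of the list mean per tumour the milk protein difference was 0.56 (two-sided p = 0.0145, adjusted over 27 lists 0.392), with each of the 3 backgrounds in the same direction. The 3 measured AP-2 transcription factor genes, regulators of mammary epithelium, had a mean of -0.39, led by Tfap2b at -0.83 ± 0.36, and 17 of 18 interferon response genes lay higher, with a mean of 0.30. Both lists had an adjusted p of 0.0424 with the preset. With an estimated correlation the adjusted p was 0.289 and 0.968, and each of these 2 calls ended in 9 of the 16 fits that left out 1 tumour. The interferon mean was 0.027 without passage 2 control replicate 2 and 0.038 without passage 1 control replicate 2. Of 11 other settings, the AP-2 call held in 5, with means from -0.565 to -0.166, and the interferon call in 6, from -0.014 to 0.44. By exact permutation the interferon difference was 0.087 (p = 0.83) and that of milk lipid synthesis 0.208 (p = 0.0635). The AP-2 difference by the same permutation was -0.381 (p = 0.0375, adjusted over 27 lists 0.506), with each of the 3 backgrounds in the same direction.

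The remaining 23 lists were not called, each with an adjusted p of 0.968 with an estimated correlation. Mean differences were 0.007 for RANK pathway components, 0.03 for NF-kB targets, -0.05 for luminal progenitor markers, -0.05 for hormone-sensing markers, -0.003 for general luminal markers, 0.06 for basal markers, 0.11 for squamous markers and -0.04 for stem cell markers. Proliferation genes differed by 0.03 with 17 of 30 higher, apoptosis regulators by -0.03, epithelial-mesenchymal transition genes by 0.004, and immediate early genes by 0.05. Hypoxia genes differed by 0.001 and steroid response genes by 0.004. Among markers of other cell types the means were 0.014 for fibroblasts, 0.15 for adipocytes with 13 of 14 higher, 0.04 for endothelium, 0.005 for macrophages, 0.06 for neutrophils, -0.06 for T and NK cells, -0.04 for B cells, -0.03 for erythroid cells and -0.05 for skeletal muscle. Within these lists, adjusted over the list alone, Abcg2 rose (0.50 ± 0.13, SE, a stem cell marker that is also on the milk protein list) and Bcl2 fell (-0.34 ± 0.07).

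**Figure D2:**
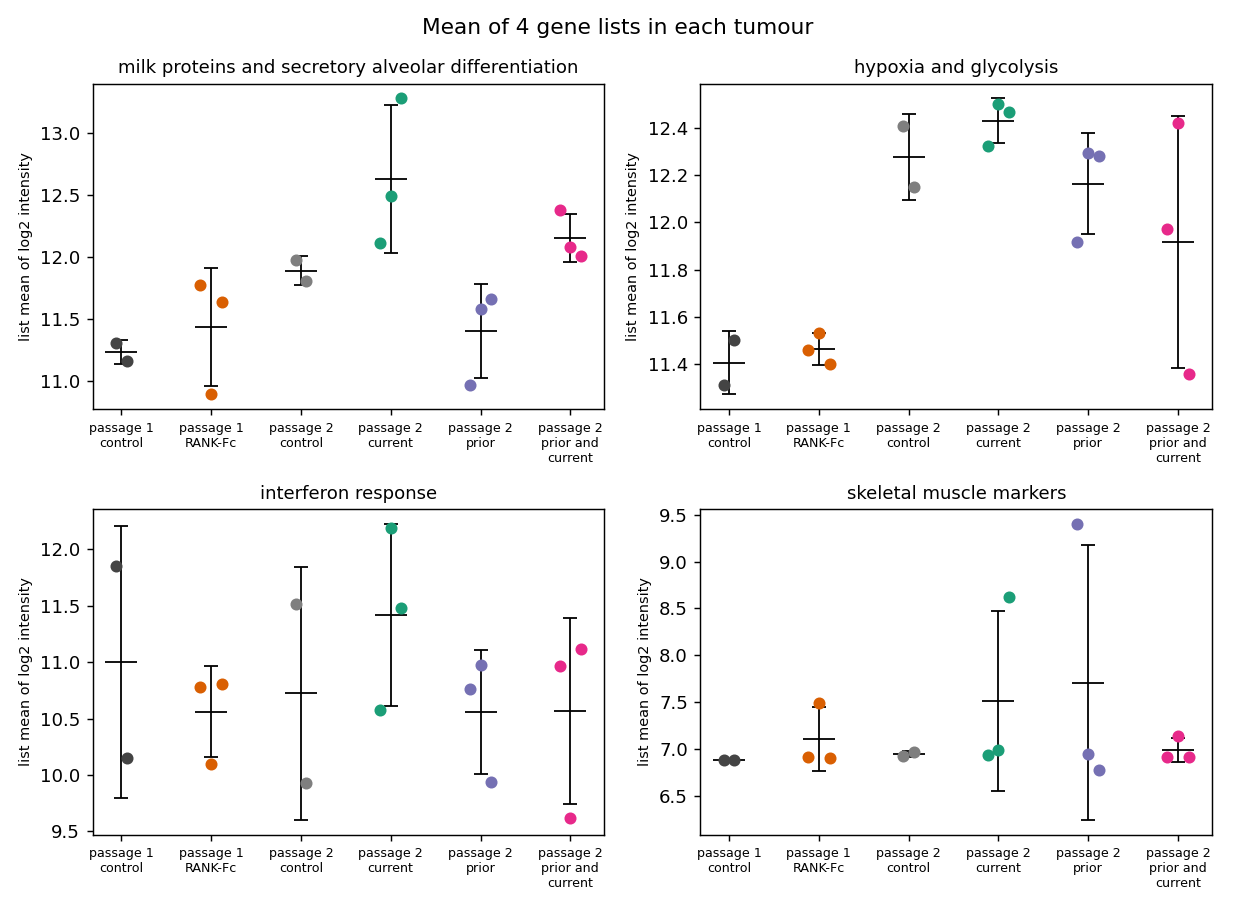
Points are single tumours. The vertical axis is the mean normalised log2 intensity of the genes of 1 list, bars are the group mean and whiskers its SD. Milk protein means lie between 12.11 and 13.28 in the 3 tumours with current RANK-Fc and at 11.81 and 11.97 in the passage 2 controls. 2 tumours stand apart in skeletal muscle markers, at 8.62 and 9.40, and interferon means spread from 9.62 to 12.19.

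In passage 1, 3 tumours with RANK-Fc were compared with 2 controls, and no gene passed the limma test. Pip was again first, at 2.54 ± 0.41 (SE, adjusted p = 0.565), with 13.06 or more in the 3 treated tumours against 9.69 and 12.47 in the controls. Others on the higher side were Rnase2a at 1.37 ± 0.35, Cadm4 at 0.46 ± 0.12, Serp1 at 0.44 ± 0.11 and Ttyh1 at 0.40 ± 0.08. On the lower side were Fam169b and Fxyd2 at -0.51 each, Abca5 at -0.45, the ubiquitin ligase gene Btrc at -0.41 and R3hdml at -0.31. With the preset correlation, milk proteins (mean 0.33, 23 of 32 higher), milk lipid synthesis (0.06, 18 of 24) and proliferation (0.12, 26 of 30) were called higher and adipocyte markers lower (-0.56, 13 of 14). Each had an adjusted p of 0.908 with an estimated correlation, and no member passed over its list alone. The milk protein call ended in 3 of 5 fits that left out a tumour, at 0.129 without RANK-Fc replicate 1, 0.234 without RANK-Fc replicate 3 and 0.294 without control replicate 2. It held in 9 of 11 other settings, with a mean of 0.082 with median centring, where it ended. The milk lipid mean turned to -0.073 without RANK-Fc replicate 1, to -0.094 without control replicate 2 and to -0.012 with median centring, and its call ended in each. It also ended without RANK-Fc replicate 3 (0.073). The proliferation call ended without control replicate 2 (0.062) and the adipocyte call without RANK-Fc replicate 3 (-0.412). There were 220 genes with an unadjusted p under 0.05, fewer than the 707 expected by chance. With 3 tumours against 2, the lack of calls is weak evidence of no effect. The count past the threshold was 0 in the 13 other settings and 4 without passage 1 control replicate 2. The adipocyte difference became 0.25 without passage 1 control replicate 1, whose adipocyte mean of 10.74 stood above 8.62 in the other control.

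In passage 2, 3 tumours with current RANK-Fc were compared with 2 controls, and again no gene passed the limma test, with 554 genes at an unadjusted p under 0.05 and 0 past the threshold in each of the 13 other settings. Chance alone would put 707 genes at such an unadjusted p. The first on the higher side were Armcx3, a mitochondrial protein gene, at 1.08 ± 0.17 (SE, adjusted p = 0.278, its other probe at 0.29) and Lcn10 at 1.25 ± 0.20 (adjusted p = 0.278). Lcn10 was not above background in the controls. Its group means lay 2.35-fold apart, a point value without sampling error. Cyb5b followed at 0.71 and Cyp51 at 0.49. On the lower side were the fibroblast growth factor receptor gene Fgfr3 at -1.31 ± 0.31 (its other probe at -0.37), the lipase gene Mgll at -1.0 ± 0.20 (3 probes, the highest at -0.69), Rufy4 at -0.52 (adjusted p = 0.999), Obi1 at -0.51 and the chromatin remodeller gene Atrx at -0.41 (3 probes, the highest at 0.02). Rufy4 was not above background with current RANK-Fc. It stood 1.46-fold lower by the group means and 1.43-fold in the fit, which weighs tumours that share an array. The count was 4 without passage 2 control replicate 1 and 2 without current replicate 1.

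With the preset correlation 12 lists were called in this comparison, 11 of them higher: interferon response (mean 1.015, 18 of 18 members), milk proteins (0.745, 29 of 32), fibroblast markers (0.66, 20 of 20), squamous markers (0.48), epithelial-mesenchymal transition (0.37), macrophages (0.345, 16 of 16), NF-kB targets (0.33), basal markers (0.30), milk lipid synthesis (0.27), hypoxia (0.18) and endothelium (0.15). The AP-2 list was lower (-0.84), and Tfap2b (-1.95 ± 0.63, SE) and Tfap2a (-0.43 ± 0.18) fell when adjusted over the list alone. The AP-2 call held in 9 of 11 other settings, with means from -1.384 to -0.289. With an estimated correlation the adjusted p lay between 0.292 and 0.750. Current replicate 3 stood apart: its fibroblast mean was 11.215 against 9.58 and 9.44 in the other current tumours, its squamous mean 9.25 against 8.13 and 8.14, its muscle marker mean 8.62 against 6.93 and 6.99, and its Tfap2b level 6.47 against 9.86 and 8.18. Without it the fibroblast difference was 0.155 (adjusted p = 0.172 with the preset), and the basal, squamous, epithelial-mesenchymal, endothelial and macrophage calls ended as well, at means of 0.12, 0.17, 0.11, 0.05 and 0.14. The basal (0.272), squamous (0.355) and endothelial (0.081) calls ended without passage 2 control replicate 1 too, the epithelial-mesenchymal (0.246) and macrophage (0.234) calls without passage 2 control replicate 2, and the macrophage call without current replicate 2 (0.241). The interferon call ended without passage 2 control replicate 2, at 0.29 (adjusted p = 0.482 with the preset). Without current replicate 3 the milk protein mean was 0.428 and the milk lipid mean 0.132, and the milk lipid call ended without passage 2 control replicate 1 (0.226, adjusted p = 0.0809 with the preset). The NF-kB call ended without current replicate 2 (0.125, adjusted p = 0.462) and without passage 2 control replicate 2 (0.24, 0.0621), and the hypoxia call held in 1 of 5 fits that left out a tumour.

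Treatment in the earlier passage was asked about in passage 2 tumours, first as prior RANK-Fc alone (3 tumours) against controls (2). Pip was higher by 3.49 ± 0.41 on the log2 scale (SE, 3.25 to 6.01 in other settings, adjusted p = 0.0226), at 9.10 or more in the 3 treated tumours against 5.95 and 6.59 in the controls, and was the single gene past the threshold. For Pip, 1 of the 2 controls was not above background, so no fold is given for it. There were 1081 genes at an unadjusted p under 0.05. Below it came Chadl at 3.02 ± 0.46 (adjusted p = 0.0905), the growth factor gene Nrg2 at 1.81 ± 0.25 (0.0529, its other probe at 0.09), the carboxypeptidase gene Cpd at 1.06 ± 0.16 (0.0905, its other probe at 0.59) and Tspan3 at 0.73 ± 0.12 (0.0905), which did not pass. On the lower side Fer1l4 stood at -1.19, the bone morphogenetic protein antagonist gene Chrdl2 at -1.15, Akap12 at -0.77 (its other probe at -0.26), Mapk4 at -0.63 (not above background with prior RANK-Fc, at least 1.56-fold lower by the group means and 1.55-fold in the fit) and Snx18 at -0.46, with adjusted p from 0.111 to 0.184. Milk proteins (-0.46, 29 of 32 lower), adipocyte markers (-0.52, 14 of 14) and T and NK cell markers (-0.38, 17 of 18) were called lower with the preset, and each had an adjusted p of 0.865 with an estimated correlation. Each of these 3 calls ended in 2 of 5 fits that left out a tumour. Without passage 2 control replicate 1 the means were -0.477, -0.178 and -0.26. Without prior replicate 1 milk proteins stood at -0.287 and adipocyte markers at -0.292, and without prior replicate 3 T and NK cell markers stood at -0.17. Adjusted over the list alone, Aqp5 (0.82 ± 0.19), the luminal progenitor markers Tspan8 (2.72 ± 0.74) and Itgb3 (1.03 ± 0.30), Cd200 (1.46 ± 0.33), the oxytocin receptor gene Oxtr (1.19 ± 0.30) and Nr4a1 (1.11 ± 0.21) rose. The count of 1 became 0 without prior replicate 1 or 2 or without passage 2 control replicate 2, 3 without prior replicate 3 and 4 without passage 2 control replicate 1. It was 0 with no background subtraction, with a filter on all channels, with no dye term, with log ratios alone and with the groups compared alone, 2 with quantile normalisation or a trended variance, 3 with median centring and 5 with the uncorrected intraspot correlation. Pip passed in 8 of 12 other settings. In the 6 fits that left out tumours its log2 difference ran from 3.19 to 3.88, and in most of them it did not pass.

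With RANK-Fc in both passages (3 tumours against 2 controls), 10 genes rose and 1 fell. The secretoglobin genes Scgb1b27, Scgb1b30, Scgb2b2 and Scgb2b20, which code for small secreted proteins related to androgen-binding protein, rose by 5.64 ± 0.71 (SE, 49.97-fold, adjusted p = 0.00656), 5.31 ± 0.75, 5.18 ± 0.58 and 5.12 ± 0.59. The other probe of Scgb1b30 stood at 0.80, and the mean of its 2 probes, at 3.07, did not pass (adjusted p = 0.0519). Pip rose by 5.21 ± 0.43 (adjusted p = 0.000392), and by 4.90 to 7.82 in other settings. The peptide transporter gene Slc15a2 fell by 1.10 ± 0.18 (adjusted p = 0.0449). Slc15a2 passed in 1 of 5 fits that left out a tumour and in 6 of 13 other settings. Of the 5 fits, Scgb1b30, Scgb2b2 and Scgb2b20 passed in 3, Scgb1b27 in 4 and Pip in 5. In each of these genes the 3 treated tumours lay beyond both controls. Fgfr3 at -1.91 ± 0.32 (adjusted p = 0.0575, its other probe at -0.50), Chrdl2 at -1.38, Gdpd3 at -1.36 and the interleukin 6 receptor gene Il6ra at -0.78 did not pass. Macrophage markers (-0.39, 14 of 16 lower), T and NK cell markers (-0.51, 17 of 18) and hypoxia genes (-0.39, 14 of 19) were called lower with the preset, each with an adjusted p of 0.909 with an estimated correlation. The hypoxia mean was -0.065 without prior and current replicate 3 (adjusted p = 0.822 with the preset) and -0.342 without passage 2 control replicate 1, where the macrophage mean was -0.285. T and NK cell markers stood at -0.238 without prior and current replicate 2. Each of these calls ended there. Adjusted over the list alone, Nr4a1 (1.34 ± 0.22), Arg1 (1.34 ± 0.37), Aqp5 (0.91 ± 0.20), Insig1 (0.88 ± 0.19) and Scd2 (0.49 ± 0.13) rose and the complement gene C1qc (-0.81 ± 0.24) fell. The count of 11 became 24 without prior and current replicate 1 and 1 without passage 2 control replicate 2. It was 0 with no dye term, 0 with log ratios alone, 5 with the groups compared alone and 20 with the uncorrected intraspot correlation.

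Current RANK-Fc was also compared within tumours with prior RANK-Fc (3 against 3), and no gene passed the limma test, with 1399 genes at an unadjusted p under 0.05 and 0 past the threshold in each of the 13 other settings. The named genes all had an adjusted p of 0.165. On the higher side were Scgb2b2 at 2.51 ± 0.50 (SE), Scgb2b27 at 2.35 ± 0.45 (its other probe at 1.75), Scgb2b15 at 1.65 ± 0.29, Asns at 0.83 ± 0.15 and Cyp51 at 0.53 ± 0.11. On the lower side were Ramp1 at -0.96 (3 probes, the highest at -0.12), the chemokine gene Cx3cl1 at -0.81, Sh3bp1 at -0.80 (3 probes, the highest at -0.08), Bcl2 at -0.71 and Notch2 at -0.70. Milk proteins (0.65, 28 of 32 higher), milk lipid synthesis (0.33, 17 of 24) and adipocyte markers (0.83, 14 of 14) were called higher with the preset, and epithelial-mesenchymal transition (-0.25), fibroblast (-0.43), macrophage (-0.28) and hypoxia lists (-0.29) lower. Each had an adjusted p of 0.820 with an estimated correlation. Adjusted over the list alone, 6 milk protein genes rose, among them Csn1s2a (3.28 ± 1.06) and Wap (1.36 ± 0.45), and 1, Mfge8 (-0.88 ± 0.28), fell. The fibroblast difference was -0.14 without prior replicate 1, whose muscle marker mean was 9.40 against 6.95 and 6.78 in the other prior tumours, and the adipocyte difference was 0.19 without prior and current replicate 3, where the hypoxia mean turned to 0.04 (adjusted p = 0.295 with the preset). The hypoxia call ended in 3 of 6 fits that left out a tumour, also without prior replicates 2 (-0.171) and 3 (-0.201). The epithelial-mesenchymal call ended in 4 of 6, at -0.169 and -0.226 without prior replicates 1 and 3 and at -0.234 and -0.189 without prior and current replicates 1 and 2. The fibroblast call ended in 3, also at -0.357 and -0.377 without prior and current replicates 1 and 2. The macrophage call ended in 2, at -0.221 without prior replicate 1 and -0.234 without prior and current replicate 2. The gene count was 26 without prior and current replicate 2 and 1 without prior replicate 3.

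Averaged over both passage 2 backgrounds (6 tumours with prior RANK-Fc against 5 without), 38 genes rose and 13 fell. Scgb1b27 rose by 4.09 ± 0.49 (SE, 17.0-fold, adjusted p = 0.00318), Pip by 4.04 ± 0.29 (adjusted p = 9.18e-05, 3.72 to 6.38 in other settings), Scgb1b30 by 3.91 ± 0.52 (its other probe by 0.47), and Scgb2b20 and Scgb2b2 by 3.81 ± 0.41 and 3.81 ± 0.40 (adjusted p = 0.00189 for both). In passage 1 controls, by comparison, Pip stood at 11.08 ± 1.97 (SD, n = 2) and Scgb1b27 at 12.15 ± 2.85, against 6.27 ± 0.45 and 6.78 ± 0.06 in passage 2 controls. Nr4a1, an immediate early nuclear receptor gene, rose by 1.01 ± 0.15 (adjusted p = 0.0162). Fer1l4 (-1.07 ± 0.18), the amino acid transporter gene Slc43a2 (-1.05 ± 0.20), the metalloprotease gene Adam8 (-1.0 ± 0.19) and Gdpd3 (-0.99 ± 0.17) fell. Lcn10 also passed on the lower side, at a fitted -0.79 that is no exact fold: it was above background in 1 of the 6 tumours with prior RANK-Fc and in neither passage 2 control, so the value rests on the current group, at 7.76. Of the 12 fits that left out tumours, Adam8 and Lcn10 passed in 2, Slc43a2 in 3, Gdpd3 in 4, Fer1l4 in 5 and Nr4a1 in 9, and Adam8 passed in 4 of 13 other settings. All 10 genes that rose with prior and current RANK-Fc, and Pip from the comparison of prior RANK-Fc alone, were among the 38. The labels do not say which passage 1 tumour each transplant came from, so source tumour and prior treatment were not separated.

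**Figure D3:**
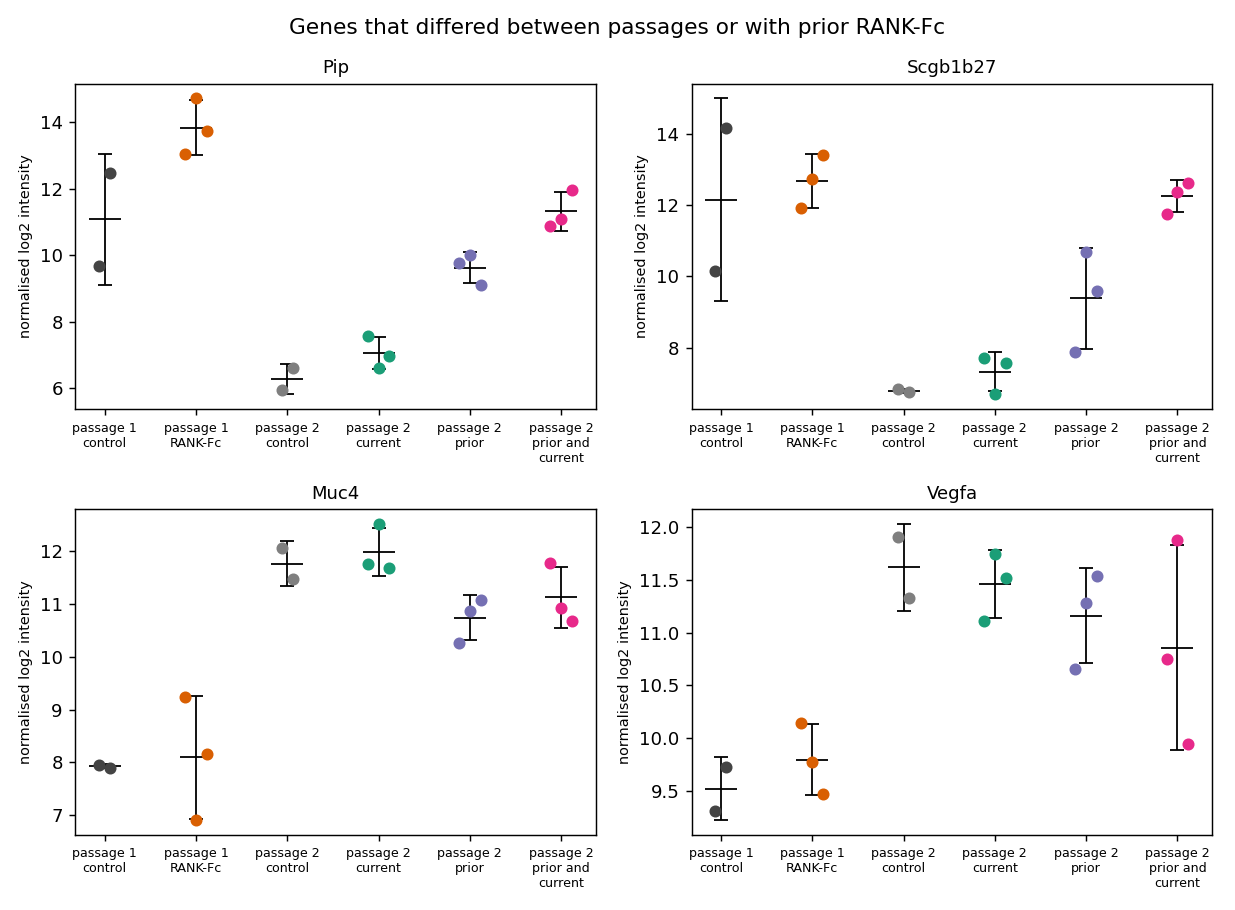
Points are single tumours. The vertical axis is the normalised log2 intensity of 1 gene, bars are the group mean and whiskers its SD. Pip lies at 9.10 or more in the 6 passage 2 tumours with prior RANK-Fc and at 7.57 or less in the 5 without it, Scgb1b27 at 7.88 or more and 7.71 or less, and in controls Muc4 lies at 11.47 or more in passage 2 and 7.95 or less in passage 1, Vegfa at 11.33 or more and 9.73 or less.

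With prior RANK-Fc averaged, 8 lists were called lower with the preset correlation and none higher: milk proteins (-0.51, 28 of 32 lower), epithelial-mesenchymal transition (-0.25), endothelium (-0.20), macrophages (-0.42, 15 of 16), neutrophils (-0.335), T and NK cells (-0.53, 17 of 18), interferon response (-0.62, 18 of 18) and hypoxia (-0.33, 17 of 19). With an estimated correlation the adjusted p lay between 0.732 and 0.932. By exact permutation of the list means p was 0.04 for milk proteins, 0.045 for endothelium and 0.045 for neutrophils, each with an adjusted p of 0.405 over 27 lists. It was 0.11 for T and NK cells, 0.125 for hypoxia, 0.2 for macrophages, 0.31 for interferon response and 0.485 for epithelial-mesenchymal transition. The interferon mean was -0.201 without passage 2 control replicate 1 (adjusted p = 0.509 with the preset) and -0.278 without prior and current replicate 2. Without current replicate 3 the epithelial-mesenchymal mean was -0.077, the endothelial -0.131, the neutrophil -0.227 and that of milk proteins -0.304, and the first 3 of these calls ended. The epithelial-mesenchymal call also ended without passage 2 control replicate 1 (-0.173) and prior replicate 2 (-0.139), and the neutrophil call without passage 2 control replicate 2 (-0.257) and prior and current replicate 3 (-0.217), where the hypoxia mean was -0.17. Without both tumours with muscle signal the milk protein mean was -0.204 (adjusted p = 0.147 with the preset). Adjusted over the list alone, 7 of 16 macrophage genes fell, among them Cd68 (-0.75 ± 0.20, SE), Csf1r (-0.60 ± 0.19) and C1qc (-0.59 ± 0.16), while Arg1 rose (0.90 ± 0.25). In the same way Lalba (-1.33 ± 0.36), Cel (-1.31 ± 0.36) and Plin2 (-0.62 ± 0.16) fell and Aqp5 (0.64 ± 0.14) rose among milk proteins. Slc2a1 (-0.67 ± 0.17), Ndrg1 (-0.77 ± 0.23) and Pdk1 (-0.35 ± 0.10) fell among hypoxia genes, and Clec4e and Padi4 fell among neutrophil genes. Oxtr (1.04 ± 0.22) and Tfap2b (1.47 ± 0.45) rose, and Tnfrsf11a (-0.53 ± 0.14) and Thy1 (-0.58 ± 0.13) fell. The gene count of 51 was 10 with no dye term, 11 with the groups compared alone, 0 with log ratios alone and 132 with the uncorrected intraspot correlation. It was 263 without current replicate 1, 110 without prior and current replicate 1, 27 and 25 without prior and current replicates 3 and 2, 26 and 18 without prior replicates 1 and 2, 20 without current replicate 3, and 19 and 18 without passage 2 control replicates 1 and 2. It was 12 without the 2 tumours with muscle signal. Scgb2b2 and Scgb2b20 passed in 12 of 13 other settings and Pip in 11 of 12, and these 3 passed in all 12 fits that left out tumours.

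Whether the effect of current RANK-Fc depended on prior RANK-Fc was tested as an interaction, and no gene passed the limma test (946 genes at an unadjusted p under 0.05, 0 in each of the 13 other settings, 4 without current replicate 2 and 1 without passage 2 control replicate 1). The smallest p belonged to Rftn1 at -1.48 ± 0.26 (SE, adjusted p = 0.505), followed by Cx3cl1 at -1.10, Exoc3l4 at -0.94, Armcx3 at -1.11 and Mtmr7 at -1.69 (the other probes of these last 2 at -0.13 and -0.64). On the other side were Mgll at 1.14 (3 probes, the lowest at 0.83), Cables1 at 1.06, Entpd3 at 0.67, and Gm9 and Rufy4 at 0.60. Of the lists 9 were called lower and 1 higher with the preset, and none was called with an estimated correlation. Fibroblast markers had the lowest adjusted p (9.31e-08, mean -1.09, 20 of 20 lower) and an adjusted p of 0.516 with an estimated correlation. Their mean was -0.496 without current replicate 3 and -0.267 (adjusted p = 0.0424 with the preset) without both tumours with muscle signal. Cd200 was lower (-1.77 ± 0.42) and passed when adjusted over the list alone.

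Whether the effect of RANK-Fc differed between passages was tested as the effect in passage 2 minus that in passage 1, and no gene passed the limma test (250 genes at an unadjusted p under 0.05, 0 in each of the 13 other settings, 2 without passage 2 control replicate 1 and 1 without passage 1 control replicate 2). Armcx3 at 1.21 ± 0.23 (SE, its other probe at 0.58), Hcar2 at 1.05, the small heat shock protein gene Cryab at 0.88, Fam169b at 0.74 and Btrc at 0.51 were first on the higher side. First on the lower side were Pip at -1.93 ± 0.57, Fgfr3 at -1.24 (its other probe at -0.46), Tacc2 at -0.61, the zinc transporter gene Slc30a6 at -0.48 and Gm9 at -0.46. Each had an adjusted p of 1. The 250 genes at an unadjusted p under 0.05 were fewer than the 707 expected by chance. With the preset, 10 lists were called higher and 1 lower, and none was called with an estimated correlation. Interferon response had the lowest adjusted p (4.9e-08, mean 1.31, 18 of 18 higher) and an adjusted p of 0.581 with an estimated correlation. Its mean was 0.563 without passage 1 control replicate 1 (adjusted p = 0.0944 with the preset) and 0.628 without passage 2 control replicate 2 (0.0692), and the call ended in both.

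Passage 2 controls (2 tumours) differed from passage 1 controls (2 tumours) in 463 genes, of which 132 rose and 331 fell with passage. The mucin gene Muc4 rose by 3.85 ± 0.46 (SE, 14.4-fold, adjusted p = 0.0022, its other probe by 1.28), Galnt9, a gene of mucin-type glycosylation, by 3.42 ± 0.57, the gap junction gene Gjb2 by 2.99 ± 0.47, the milk lipase gene Cel by 2.98 ± 0.58 and the protease inhibitor gene Cst6 by 2.83 ± 0.62. Scgb1b27 fell by 5.42 ± 0.78 (42.9-fold) and Pip fell by 4.87 ± 0.47 (adjusted p = 0.000795). The log2 change of Pip ran from -7.27 to -4.63 in other settings and from -5.84 to -3.90 in fits that left out a control. Scgb1b30, Scgb2b2 and Scgb2b20 also fell, with log2 changes of -5.38 ± 0.82, -4.66 ± 0.64 and -4.64 ± 0.65, and the other probe of Scgb1b30 stood at -0.95. The mean of the 2 Muc4 probes was 2.56. Of 4 limma fits that left out a control, Cel and Cst6 passed in 0, Galnt9, Gjb2, Scgb1b30 and Scgb2b20 in 2, Muc4, Scgb1b27 and Scgb2b2 in 3 and Pip in 4. Of the 38 genes that rose with prior RANK-Fc averaged, 30 fell here, and of the 13 that fell, 5 rose. The passage 2 controls are part of both comparisons, so this overlap is not independent.

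Of 19 genes of low oxygen response, 5 rose with passage over all genes and the other 14 did not pass, and 9 rose when adjusted over the list alone, with Adm at 2.13 ± 0.50 (SE), the vascular growth factor gene Vegfa at 2.01 ± 0.45 and Ndrg1 at 1.89 ± 0.37. The list mean was 0.85 (adjusted p = 7.01e-10 with the preset, 0.505 with an estimated correlation). Hormone-sensing luminal markers had 4 members that fell, with the transcription factor gene Foxa1 at -2.14 ± 0.35 and at least 4.19-fold lower, Cd200 at -2.03 ± 0.37 and Cited1 at -1.57 ± 0.34 (list mean -0.565, adjusted p = 0.00368 with the preset and 0.207 with an estimated correlation). Luminal progenitor markers had 3 that fell, Tspan8 (-4.42 ± 0.84), Itgb3 (-2.69 ± 0.34, its other probe -0.85) and Kit (-1.12 ± 0.26), and the list was not called. Cel and Plin2 (1.67 ± 0.25) rose and Aqp5 (-1.59 ± 0.22) fell among milk proteins, a list called higher (0.70, adjusted p = 0.853 with an estimated correlation). The Wnt target gene Axin2 (1.46 ± 0.26, at least 2.91-fold by the group means and 2.75-fold in the fit, its other probe 0.42) and Myc (0.76 ± 0.19) rose and the Notch target gene Hey1 (-2.46 ± 0.47) fell among stem cell markers. RANK itself, Tnfrsf11a, was higher by 0.84 ± 0.22 and passed over its list alone, with an adjusted p of 0.0605 over all genes. Single members of other lists also changed: Lpin1 (0.68), Bmf (0.95) and Tgfb2 (0.98) rose, and Oxtr (-2.07), Nr4a1 (-1.47), Sfrp1 (-0.87) and Bcl2 (-0.63) fell. Of the genes named in this paragraph as passing, Adm, Vegfa, Ndrg1, Tspan8, Kit, Cd200, Cited1, Cel, Hey1, Myc, Bmf, Sfrp1 and Bcl2 passed over all genes in 0 of the 4 limma fits that left out a control, and Foxa1, Axin2, Lpin1 and Tgfb2 passed in 1. Squamous markers (0.44, 12 of 12 higher) and proliferation (0.12, 26 of 30) were called higher, and fibroblast (-1.0, 19 of 20 lower) and adipocyte markers (-1.10) lower, each with an adjusted p of 0.853 with an estimated correlation. Without passage 1 control replicate 1 the adipocyte mean was -0.311 (adjusted p = 0.867 with the preset) and the squamous mean 0.353. Without passage 2 control replicate 2 the adipocyte mean was -0.802, the squamous 0.292 and the proliferation mean -0.059, and without passage 1 control replicate 2 proliferation stood at 0.065. Each of these calls ended there. With 2 tumours per group a single tumour weighed heavily: the count was 63 and 91 without passage 1 control replicates 1 and 2, and 182 and 11 without passage 2 control replicates 1 and 2, fits in which the lone control was taken to vary like the other groups. It was 271 with median centring in place of loess, 306 with no dye term and 0 with log ratios alone.

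Whether the genes that moved with RANK-Fc in passage 1 moved alike in passage 2, in other animals, was tested on the 100 genes highest and the 100 lowest in passage 1. The 2 passages were not fully separate. Passage 1 RANK-Fc replicate 1 shared an array with current replicate 1, and replicate 2 with prior replicate 1. Passage 1 control replicate 2 shared one with prior and current replicate 1. Tumours with prior RANK-Fc may also have grown from the same passage 1 tumours, which the labels do not say. In the higher set, 78% of 99 genes were also positive with current RANK-Fc in passage 2, with a median of 0.10 that did not pass fry after adjustment over 10 tests (adjusted p = 0.0730). The same genes had a median of 0.16 with prior and current RANK-Fc, 72% of them positive, and passed (adjusted p = 0.0232). With prior RANK-Fc alone the median was 0.08 (adjusted p = 0.0752). The lower set had a median of -0.03 with current RANK-Fc in passage 2 (adjusted p = 0.183). Across the 14147 genes, log2 differences of passage 1 correlated with those of current RANK-Fc in passage 2 at r = 0.063 and Spearman's rho = 0.074. Of 100 regroupings of the tumours, the real one included, 77 gave an r as large in absolute value, of either sign. With prior and current RANK-Fc r was 0.209 (41 of 100 regroupings), with current after prior RANK-Fc 0.137 (58 of 100) and with prior RANK-Fc 0.094 (67 of 100).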

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

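In 21 cases a fixed gene list differed, by a test of the difference itself, between 2 effects of RANK-Fc. The tests were planned, and the fit without both tumours with skeletal muscle signal was chosen after seeing the data. With an estimated correlation the adjusted p lay between 0.516 and 0.762, so none of the 21 held by that test.

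The effect of current RANK-Fc after prior RANK-Fc was lower than its effect without prior RANK-Fc for fibroblast markers by a mean log2 difference of -1.09 (adjusted p = 9.31e-08 with the preset correlation and 20 of 20 genes). It was also lower for skeletal muscle markers (-1.15, adjusted p = 0.0364), interferon response (-0.84, 0.00395), squamous markers (-0.66, 0.00669), epithelial-mesenchymal transition (-0.62, 6.16e-05), macrophage markers (-0.62, 1.39e-05), hypoxia genes (-0.47, 0.000418), NF-kB targets (-0.44, 0.00395) and basal markers (-0.43, 0.00605). It was higher for adipocyte markers (0.64, 0.00875). In current replicate 3 the muscle marker mean was 8.62 and in prior replicate 1 it was 9.40, against 6.78 to 7.14 in the other passage 2 tumours. Without both, the muscle difference was 0.09, fibroblast markers stood at -0.267 (adjusted p = 0.0424 with the preset) and 5 further calls besides muscle ended: epithelial-mesenchymal transition at -0.26 (0.111), squamous markers at -0.306 (0.145), basal markers at -0.215 (0.115), interferon response at -0.578 (0.101) and adipocyte markers at 0.326 (0.116). Leaving out current replicate 3 alone gave -0.496 for fibroblast markers, -0.316 for epithelial-mesenchymal transition, -0.386 for macrophage markers, and ended the basal (-0.22), squamous (-0.298) and muscle (-0.586) calls. Interferon response was -0.163 without passage 2 control replicate 2 and -0.185 without prior and current replicate 2, NF-kB targets -0.247 without current replicate 2, and without prior and current replicate 3 hypoxia genes were -0.129 and adipocyte markers -0.014, and each of these calls ended. The muscle call ended in 7 of the 11 fits that left out 1 tumour, with a mean of -0.408 without prior replicate 1.

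The effect of RANK-Fc in passage 2 was higher than in passage 1 for interferon response by a mean log2 difference of 1.31, with 18 of 18 genes higher. It was also higher for fibroblast markers by 0.85, adipocyte markers by 0.75, epithelial-mesenchymal transition by 0.48, squamous markers by 0.47, NF-kB targets by 0.46, macrophage markers by 0.40, T and NK cell markers by 0.39, basal markers by 0.30 and endothelial markers by 0.23. It was lower for proliferation, at -0.14, with 28 of 30 genes lower. Without passage 1 control replicate 1 the interferon difference was 0.563 (adjusted p = 0.0944 with the preset), the adipocyte difference -0.10, the basal difference 0.06 and the endothelial difference 0.043. Without current replicate 2 the T and NK cell difference was 0.06 and that of NF-kB targets 0.282. Without passage 2 control replicate 2 the interferon difference was 0.628 (adjusted p = 0.0692 with the preset) and the proliferation difference 0.05. Without current replicate 3 the fibroblast difference was 0.364 and the squamous, epithelial-mesenchymal and macrophage differences 0.163, 0.231 and 0.205. Apart from the fibroblast call, each call named with such a fit ended there.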

How the results depend on the processing

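The uncorrected intraspot correlation and the fit without both tumours with skeletal muscle signal were chosen after seeing the data, as was the permutation of list means. No paired analysis was possible because the labels carry animal identifiers and no replicate numbers shared between groups. The deposited normalised table and a slide or scan block were planned and not run, since its columns match no label and there was 1 slide and 1 scan. Lists were not tested on log ratios alone or on the groups compared alone. Log ratios alone leave 2 residual degrees of freedom, and leaving out 1 of 2 controls assumes that the lone control varies like the other groups. Signal above background in 47.5% to 56.5% of spots limits dim genes.

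With limma, the counts of 0 stayed 0 in all 13 other settings for current RANK-Fc averaged, in passage 1, in passage 2 and after prior RANK-Fc, the interaction and the passage difference. Leaving out tumours gave 0 to 4 for the first 3 of these, 0 to 26 after prior RANK-Fc (26 without prior and current replicate 2), 0 to 4 for the interaction and 0 to 2 for the passage difference. The count of 1 for prior RANK-Fc in passage 2 was 0 with no background subtraction, a filter on all channels, no dye term, log ratios alone or the groups compared alone, 2 with quantile normalisation or trended variance, 3 with median centring, 5 with the uncorrected correlation and 5 without both muscle tumours. Single tumours gave 0 to 4. The count of 11 for prior and current RANK-Fc was 0 with no dye term or log ratios alone, 5 with the groups alone and 20 uncorrected. Single tumours gave 1 to 24. The count of 51 for prior RANK-Fc averaged was 10 with no dye term, 0 with log ratios alone, 11 with the groups alone, 132 uncorrected and 12 without both muscle tumours. Single tumours gave 18 to 263. The count of 463 between controls was 271 with median centring, 306 with no dye term and 0 with log ratios alone. Single tumours gave 11 to 182. Apart from the 2 residual degrees of freedom of log ratios and the fewer tumours of reduced fits, the cause was not tested.

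The 69 list calls with a preset correlation became 0 with an estimated one. Of these calls, 44 held in every other setting tested with the preset, 18 without each single tumour and 16 in both. The signature median of 0.10 ranged from 0.05 to 0.11 and passed with the uncorrected correlation (0.106, adjusted p = 0.0488). Named genes kept direction and side of the threshold in 1765 of 1917 fits with other settings (140 weaker, 9 stronger, 3 reversed) and in 1151 of 1323 that left out a tumour (143, 16 and 13).

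The direction turned in the fits below, and the cause was not tested. A list's direction is that against all other genes by camera, which turned where the mean stayed positive for basal markers, T and NK cell markers and, without passage 2 control replicate 2, interferon response. Tnfrsf11b was 0.04 with median centring, 0.02 with independent channels and -0.16 to 0.14 in fits that left out tumours, and Pgr was 0.02 with no filter. In fits that left out tumours Tnfrsf11a ranged from -0.03 to 0.10, Mylpf from -0.27 to 0.02, Cd22 from -0.09 to 0.02 and Cfd from -0.02 to 0.90. Interferon response with current RANK-Fc averaged was -0.014 with median centring and, in fits that left out tumours, from 0.027 to 0.505. The mean per tumour of milk lipid genes with prior RANK-Fc was 0.032 with median centring. In fits that left out tumours, list means ranged from -1.337 to 0.247 (adipocyte, passage 1), from -0.094 to 0.224 (milk lipid, passage 1, -0.012 with median centring), from -0.014 to 1.008 (adipocyte, interaction), from -0.514 to 0.04 (hypoxia, after prior RANK-Fc), from -0.059 to 0.299 (proliferation, controls) and from -1.702 to 0.09 (skeletal muscle, interaction, 0.09 without both muscle tumours). For the passage difference they ranged from -0.101 to 1.482 (adipocyte), 0.056 to 0.524 (basal), 0.057 to 0.652 (T and NK cell) and -0.307 to 0.051 (proliferation). Genes lower in passage 1 turned, with prior and current RANK-Fc, to 0.018 with processed intensities, 0.017 with no filter, 0.012 with the mean of probes or trended variance and 0.01 uncorrected. With prior RANK-Fc they turned to 0.021 with no background subtraction, 0.028 with no filter, 0.008 with the mean of probes, 0.003 with trended variance, 0.01 uncorrected and 0.013 with 50 genes. After prior RANK-Fc they turned to -0.02 with no background subtraction, -0.008 with a filter on all channels or 50 genes and -0.009 with no dye term. With median centring they turned to 0.033 with current and -0.033 with prior RANK-Fc averaged. Genes higher in passage 1 turned to -0.003 after prior RANK-Fc with no filter.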

Other observations

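The tests in this part were chosen after the results they bear on had been seen, and the gland marker, sterol and ATF4 tests had their predictions written before their own values were seen. Genes of cholesterol synthesis lay higher with current RANK-Fc: in a list that left out the genes whose values had prompted it, Cyp51 and Insig1 among them, 20 of 20 measured members had a positive difference. None passed over all genes, and 12 rose when adjusted over the list alone, among them Msmo1 (0.43 ± 0.12, SE), Tm7sf2 (0.37 ± 0.08), the squalene epoxidase gene Sqle (0.34 ± 0.10) and Mvd (0.29 ± 0.09). The list mean per tumour differed by 0.26 (exact permutation within backgrounds, two-sided p = 0.006, adjusted over the 2 added lists 0.012), with 0.21 in passage 1, 0.39 in passage 2 and 0.18 in passage 2 after prior RANK-Fc. That adjustment did not cover the 27 planned lists, over which the permutation p of milk proteins was adjusted. Leaving out each tumour in turn gave 0.22 to 0.29. Camera gave p = 2.51e-15 with the preset and 0.0116 with an estimated correlation.

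This pattern is a hypothesis, since the list was added because related genes had small p values and such genes are regulated together. The prediction for sterol synthesis was a list mean that is higher in 3 of 3 backgrounds with a permutation p under 0.05. The difference of 0.258 met it. The list was chosen from values of the same tumours in the same comparison, so meeting the prediction was no independent check. Higher sterol synthesis gene expression may go with current RANK-Fc, which was not tested in other tumours. Asns is also a target of the transcription factor ATF4. The 21 other ATF4 targets differed by 0.073 (exact permutation p = 0.0915), with 16 of 21 higher and none past the threshold over the list alone, by limma. That value lay below the bound of 0.1 set against a rise, but by less than its spread over the splits, a spread that was brought into the rule after the value had been seen, so an amino acid response stays open.

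The genes led by Pip and secretoglobins that passed with prior RANK-Fc averaged were set against 4 technical or chance explanations and retained passage 1 expression. Of 100 splits of the tumours within their backgrounds, the real one alone called as many genes (1 of 100, 51 genes, against 6 in the highest other split). At an unadjusted p under 0.05 by limma it had 2204 genes, and the highest other split had 2046. Chance is therefore unlikely as far as 100 splits can tell, but it is not excluded. Probes shared among paralogs would not reach the 43 of 51 genes outside the secretoglobin family, though sharing among the others stays open. Salivary or lacrimal tissue also stays open: its 18 markers had a median difference of 0.16, below the bound of 1 set against it, but they went both ways. Dcpp3 stood at 2.32 ± 1.10, Car6 at 2.06 ± 0.44, Dcpp1 at 1.73 and Dcpp2 at 1.64, against the amylase gene Amy1 at -0.09 and Prb1 at -0.17. Of the 18, 3 (Mucl2, Smgc and Bpifa2) were above background in no prior-treated tumour. The 12 above it in all 6 had a median of 0.49 (SD 0.93). This restriction was made after the values had been seen. It keeps markers by their signal in the treated tumours, so its median decides nothing. Retained passage 1 expression may account for part: differences that share no tumour correlated across genes at r = -0.24 (Spearman's rho = -0.10). But 8 of 60 splits went as low and the lowest other reached -0.397. These differences also shared arrays. Prior and current replicate 1 lay with passage 1 control replicate 2, and current replicate 2 with passage 2 control replicate 2. With a positive intraspot correlation (0.214) both pairings push r downward, so a negative r is no independent sign of retained expression. A different source tumour cannot be told apart from prior treatment, since 0 label fields name the source.

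Higher milk protein genes with current RANK-Fc were weighed against a single tumour and against adipose tissue. Without current replicate 3, whose list mean was highest at 13.28, the difference was 0.46, against 0.56 with it. That tumour enters the passage 2 background alone, so an average over 3 backgrounds could not decide whether it carried the difference. In passage 2 the fitted mean fell from 0.745 to 0.428 without it, so it carried part of the difference there. The adipocyte list differed by 0.03 per tumour (SD over the splits 0.39, added to the rule after the value had been seen) and by 0.15 in the fit, with 13 of 14 higher, and by -0.60, 0 and 0.71 in the 3 backgrounds, where milk proteins differed by 0.20, 0.74 and 0.75, so adipose tissue stays open, and a response of the tumour cells to RANK-Fc, or a different mix of secretory cells, may remain, untested.

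For current RANK-Fc averaged, the real split called 0 genes by limma, a count that 100 of 100 splits reach whatever the data, so that count decides nothing. At an unadjusted p under 0.05 it had 933 genes, and 26 of the 99 other splits had as many or more, up to 1753, so by that count chance cannot be excluded. The highest other split called 393 genes and the next 8. Such a count points to a structure of the tumours along that 1 split, and what it follows was not tested. For current after prior RANK-Fc, 10 splits are too few for a share under 0.05. The real value was 0 by limma and the highest other 0, so 10 of 10 splits reach it whatever the data. At an unadjusted p under 0.05 the real split had 1399 genes and the highest other 1654.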
